A study of Rattus norvegicus with 12 samples.

How the data were processed

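Total RNA from the prefrontal cortex of female Sprague-Dawley rats was measured on 6 Agilent 2-colour oligonucleotide arrays, each read in the Cy3 and the Cy5 channel. Per the labels, the dams received 2 injections of saline or of betamethasone (0.4 mg/kg each) on gestational day 15. The pups received saline or ketamine (35 mg/kg) on postnatal day 14, and tissue was taken on postnatal day 15, though 1 label field gives another age. Infantile spasms are named for postnatal day 14, but the sample names do not tell which groups showed them. The labels define 3 groups of 4 replicate animals: control (saline, then saline), betamethasone (betamethasone, then saline), and betamethasone with ketamine. RNA was extracted with RNeasy columns, checked on a Bioanalyzer, and amplified and labelled with a low-input 2-colour kit with spike-in RNA, per the labels. The labels give no batch, litter or array; the file headers gave the array and slide of each sample.

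Each array held 2 animals of the same group, the odd-numbered replicate in Cy3 and the even-numbered one in Cy5. The control arrays lay on 1 slide (slide A), and the 4 arrays of the other groups on a second one (slide B). The channel signals and local backgrounds were intensity values in scanner units, per the file headers, from Feature Extraction 11.5.1.1 for slide A and 11.0.1.1 for slide B; the submitters' notes name version 10.7.3.1. The array's probe coordinates were on the rn4 build. A deposited value table held a ratio for each sample: each column equalled (median spot signal minus median local background) divided by the column median, so that every column's median was 1, with no log, dye or between-array step. The columns of control replicates 1 and 2 matched the scanner data of control replicates 3 and 4 and the reverse (standard deviation of the log2 ratio 0), and that table was used only as an alternative. The processed signals were intensity values after background subtraction, detrending, and linear and lowess dye normalization, per the file headers. Values given here on the log2 scale were computed from the deposited intensity values.

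Between 71.4% and 81.5% of the 42877 non-control spots per array were well above background in each sample, no such spot was saturated, and the number of arrays, 2 per group, limited the precision. With 4 samples per group, the median standard error of a log2 change was 0.143 and the median 95% half-width 0.315. The slope of spike-in signal on known amount was 0.492 and 0.542 for the control arrays and 0.873 to 0.881 for the others. The replicate samples of 1 group had median correlations of 0.974 to 0.995 with each other.

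The mean foreground was corrected with the median local background by normexp (offset 50), control spots and outlier spots were left out, and the arrays were normalized by loess within arrays and Aquantile between arrays. Each channel was then treated as its own sample. Spots of 1 probe were averaged. The 30367 probes were named by accession (18559), by symbol (2758) or by synonym (412) from the reference tables, and 8638 kept the name in the file. Probes well above background in at least 3 of 4 samples of a group were kept (21523), and for each gene the probe with the highest mean signal over the samples was tested. This gave 18672 genes, 13481 with a symbol and 2583 with more than 1 probe. Where no sample of a group was well above background, the change is given as a bound ("at least"), from the mean of the brighter group and, in each sample of the dimmer one, the higher of the probe's own signal and the lowest signal well above background. This bound leaves out the sampling error, and for every gene named with one it equalled the estimated change. For 607 genes a sample was missing, and at least 3 values per group were required.

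Groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with a term for the dye and the array as a random block, whose estimated correlation was 0.5365. All 12 samples were in 1 model. P values were 2-sided and were adjusted over the tested genes of a comparison by the method of Benjamini and Hochberg, with a threshold of 0.05. The comparisons were betamethasone minus control, ketamine minus saline after betamethasone, betamethasone with ketamine minus control, and the genes changed by betamethasone and moved back by ketamine. The last count shares the betamethasone samples between its 2 contrasts, so it was set against 50 simulations of unchanged groups. The share of genes whose groups did not overlap was set, after the results were seen, against 100000 simulated unchanged genes with the same array correlation. The model was tested on simulated data with 50 genes at each of 4 sizes of change, and recovered 78%, 88% and 90% of those changed 2-fold in the 3 contrasts, with 5, 13 and 8 false calls.

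Lists of genes (22 pathways and 14 cell types of the brain and its surroundings, 36 in all, at least 5 members tested) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which was also run without regard to direction. Camera compares a list with the other genes, whereas fry asks only whether the list's own members differ. These tests used the genes with no missing value, after the correlation within arrays had been removed. A list passed when camera at the preset correlation gave an adjusted p under 0.05 over the 36 lists; members were also adjusted over their list alone. Named genes were the 10 largest increases and the 10 largest decreases among genes with a symbol that passed the test and whose groups did not overlap; where none passed, the 5 smallest p values in each direction; the 4 smallest p values in each list that passed; and 21 genes of glutamate, GABA, glucocorticoid and melanocortin signalling and neuronal activity, given as a group, to which the rule as fixed added 1 that is not reported here. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

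The alternatives concerned background offset, normalization and scaling, processed signals, the value table, the detection filter, the choice of probe, the dye and array terms, array means, pooling of variances, thresholds, and leaving out each sample and each array. Areas where over 10% of the spots within 10 rows and 4 columns departed by more than 1 log2 unit from the median of the other arrays were masked in further alternatives chosen after the data were seen. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9.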

Results

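The prefrontal cortex of 15-day-old female rats was compared between control animals, animals exposed to betamethasone before birth, and animals exposed to betamethasone and given ketamine the day before sampling (n = 4 animals per group, 2 animals per array). The comparisons address how prenatal corticosteroid exposure changes transcripts of the developing cortex, and whether ketamine given on postnatal day 14 moves them. The controls were alone on their slide, so slide and group cannot be told apart in both comparisons with control. Betamethasone and betamethasone with ketamine shared 1 slide. On the array of ketamine samples 1 and 2, 2.89% of the spots departed by more than 1 log2 unit from the other arrays. Areas rich in such spots held 6.55% of the array's spots, with a median departure of −0.72. Such areas also held 2.77% of the spots on the array of control samples 3 and 4. They held 3.14% on that of control samples 1 and 2, and 0.32% to 1.24% on the remaining arrays. Principal component 1 (43.3% of the variance) placed ketamine samples 1 and 2 at −54.09 and −52.17, and the other 10 samples between 6.81 and 20.08.

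**Figure D1:**
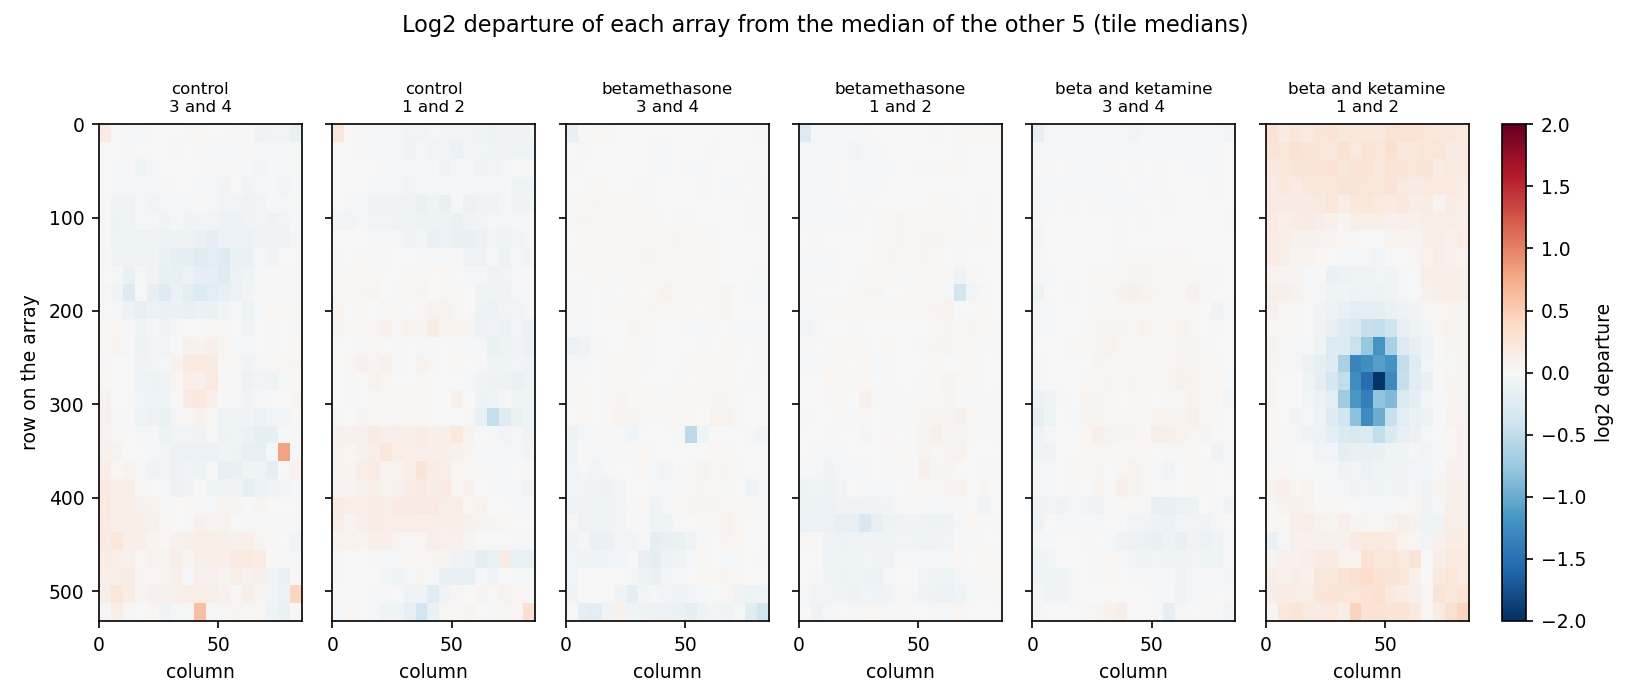
Log2 departure of each array's spots from the median of the other 5 arrays, as tile medians over the array's rows and columns. The dark area on the array of ketamine samples 1 and 2 lies near the middle of that array.

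After prenatal betamethasone, Ccng1 (cyclin G1, a p53 target) rose 7.48-fold (log2 change 2.90, SE 0.21, adjusted p = 0.000265). Its log2 intensity was 9.43 ± 0.07 in control and 12.33 ± 0.01 in betamethasone (mean ± SD, n = 4 each), from a probe on chromosome 10 (rn4, 25778638 to 25778912). Glo1, the glyoxalase that detoxifies methylglyoxal (chromosome 20, 8901397 to 8901456), rose 1.74-fold (log2 SE 0.09, adjusted p = 0.0111), from 12.43 ± 0.12 to 13.23 ± 0.04. Pdk1, which inhibits pyruvate dehydrogenase (chromosome 3, 54302974 to 54303274), rose 1.68-fold (log2 SE 0.13, adjusted p = 0.0480). Cyp11b1, the 11β-hydroxylase of corticosteroid synthesis (chromosome 7, 112977770 to 112977829), rose 1.65-fold (log2 SE 0.12, adjusted p = 0.0389). Grm4, which encodes metabotropic glutamate receptor 4 (chromosome 20, 5627795 to 5627854), fell by 0.68 on the log2 scale (SE 0.10, adjusted p = 0.0231). It went from 12.46 ± 0.18 to 11.79 ± 0.06, and its other probe was at −0.54.

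The olfactory receptor gene Or13p4 also rose (log2 change 1.64, SE 0.23, adjusted p = 0.0205), with 2 of 4 control samples well above background. Ddx56, an RNA helicase gene (0.92), Cd2bp2 (0.90), the cytidine deaminase gene Apobec1 (0.78) and the mitochondrial ribosomal gene Mrps7 (0.77) rose with adjusted p from 0.0188 to 0.0222. Hmgb4 was at least 2.04-fold higher, with no control sample well above background (adjusted p = 0.0159). Chmp4bl1 fell by 1.95 on the log2 scale (SE 0.21, adjusted p = 0.0111), from 13.04 ± 0.37 (n = 3) to 11.05 ± 0.10 (n = 4). Fbxo10, an F-box gene (chromosome 5, 61600111 to 61600170), fell by 1.35 (SE 0.16, adjusted p = 0.0126), from 10.74 ± 0.18 to 9.39 ± 0.27. Mefv, the pyrin gene, fell by 0.98 (SE 0.12, adjusted p = 0.0126), from 8.77 ± 0.11 to 7.79 ± 0.10. Rnf126, a ubiquitin ligase gene (−0.98), the RNA helicase gene Dhx9 (−0.94), the microtubule-associated Map7 (−0.82), Tmco5a (−0.79), Tmigd1 (−0.78) and the choline transporter-like Slc44a2 (−0.70) fell with adjusted p from 0.0205 to 0.0423. The other probe of Slc44a2 was at 0.24. Spots of the tested probes lay in a masked area of the array of control samples 1 and 2 for Ddx56, and of control samples 3 and 4 for Slc44a2.

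Of 18672 genes, 53 passed in limma (34 higher, 19 lower), 34 of them with a symbol and with a median change of 1.72-fold over all 53. Spots in masked areas were found for 8 of the 53. An unadjusted p under 0.05 was reached by 2320 genes. The groups did not overlap for 3350 genes (17.9%, against 2.86% by chance for independent samples), among them all 53. As 2 samples of a group share an array, chance gave 8.66% in simulations with the array correlation, and the other splits that keep arrays whole gave 3.1% and 2.65%. The count was 8 and 19 without control samples 1 and 3, and 10, 3, 6 and 11 without betamethasone samples 1, 2, 3 and 4. Leaving out an array leaves its group with 1 array, so group and array cannot then be told apart. The count was 274 and 401 without the control arrays (samples 1 and 2, samples 3 and 4), 19 and 21 without the betamethasone arrays, and 533 and 476 without the ketamine arrays, in the same order. Without single samples, Grm4 passed in 5 of 12 fits (highest adjusted p = 0.118), Pdk1 in 2 (0.203), Cyp11b1 in 1 (0.188) and Ccng1 in all 12 (0.00698). Dhx9 passed in 5, Map7 in 4, Rnf126 in 3 and Slc44a2 in 2, and each of the other named genes in 6 to 10. The array means, 2 per group, were also tested, which takes the array as the replicate. Of 26 results for named genes that passed in either comparison with control, 2 still passed and 24 did not.

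**Figure D2:**
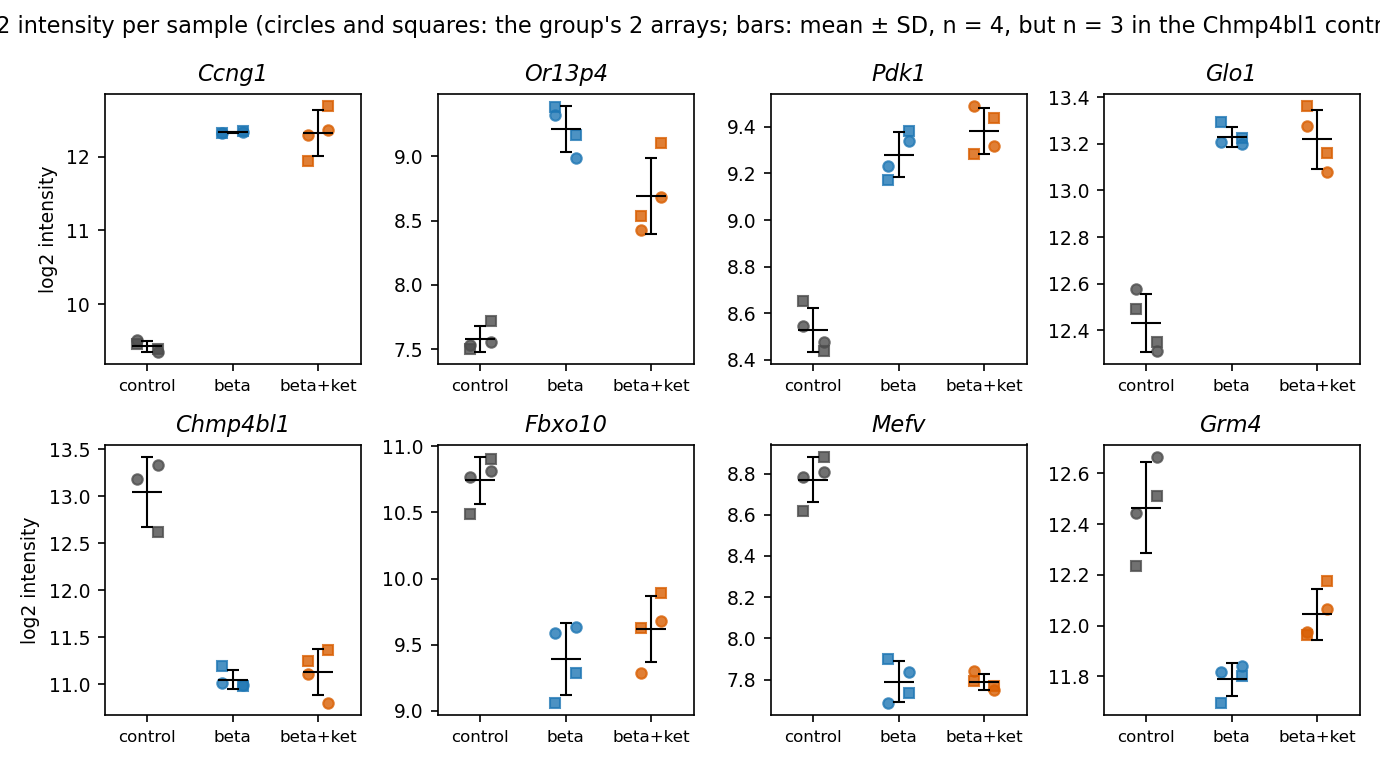
Log2 intensity of 8 named genes in each sample of the 3 groups, with the group mean ± SD. Circles and squares mark the 2 arrays of a group, with n = 4 per group except Chmp4bl1 in control, n = 3.

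Oligodendrocyte and myelin genes fell as a list after betamethasone: 20 of 23 measured members were lower, with a median log2 change of −0.25 and a mean of −0.33 (camera adjusted p = 0.00529). The adjusted p was 0.846 with an estimated correlation of 0.306, and no member passed over all genes or over the list alone. The median was below 0 under every scaling tried, which carries no weight in the deposited value table, whose scaling lowered all genes. Cldn11, a tight junction protein of myelin, was at −1.11 (SE 0.39, limma adjusted p = 0.289), with 9.40 ± 1.00 in control and 8.29 ± 0.04 in betamethasone. Part or all of its probe's spots lay in a masked area of the array of control samples 3 and 4. The myelin-associated glycoprotein gene Mag was at −0.95 (SE 0.40, other probe −0.76), Ugt8, which makes galactosylceramide, at −0.38 (SE 0.17), and the aspartoacylase gene Aspa at −0.54 (SE 0.27). The list's adjusted p was 0.0889 (median −0.19) without the array of betamethasone samples 1 and 2, and 0.0753 (median −0.26) without that of control samples 3 and 4.

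Lists related to transmission did not pass with camera in betamethasone minus control. The median of all genes was 0.03 here, 0.18 under loess with array medians of A, 0.10 under 75th percentile scaling, 0.05 with processed signals and −0.04 in the re-centred value table, so a list median above or below 0 under these is not by itself a shift of the list. Voltage-gated sodium and calcium channels had 17 of 23 members lower (median −0.14, mean −0.26, camera adjusted p = 0.172), with 0.19 under that loess. They passed only without regard to direction (fry adjusted p = 0.0255), a test that does not compare a list with other genes. Scn2a, a sodium channel of axons, was at −0.60 (SE 0.13, limma adjusted p = 0.0949, 0.0165 over the list alone). Ionotropic glutamate receptors had 16 of 27 members lower (median −0.06, with 0.19 under that loess and 0.01 under 75th percentile scaling, adjusted p = 0.357). Their auxiliary gene Neto1 was at −0.77 (SE 0.18, 0.0383 over the list alone). GABA-A and GABA-B receptors had 10 of 17 members lower (median −0.04, with 0.16 under that loess, adjusted p = 0.485). Synaptic vesicle genes had 28 of 47 lower, with a median of −0.03 and a mean of 0.08 (adjusted p = 0.592), and medians of 0.46, 0.06 and 0.01 under that loess, 75th percentile scaling and processed signals. Cell cycle genes passed only without regard to direction (fry adjusted p = 0.0255), with 14 of 26 higher (median 0.03, with −0.07 under that loess and −0.09 in the re-centred value table). The mitotic gene Birc5 was at −0.47 (SE 0.09, limma adjusted p = 0.0752, 0.0105 over the list alone). Glucocorticoid-responsive genes had 21 of 28 members higher (median 0.07, mean 0.11, with −0.01 in the re-centred value table, adjusted p = 0.413). In the deposited value table the median of all genes was −1.10, and every list just named had a median below 0.

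In betamethasone with ketamine minus control, Ccng1 rose 7.43-fold (log2 change 2.89, SE 0.21, adjusted p = 0.000274), to 12.32 ± 0.31 in the exposed group. Pdk1 rose 1.81-fold (log2 SE 0.13, adjusted p = 0.0461) and Glo1 1.73-fold (log2 SE 0.09, adjusted p = 0.0120). Coq7, of ubiquinone synthesis (chromosome 1, 176745135 to 176746315), rose 1.63-fold (log2 SE 0.10, adjusted p = 0.0288), from 9.87 ± 0.17 to 10.57 ± 0.05. Rgs12, a regulator of G-protein signalling (chromosome 14, 81363544 to 81363603), rose 1.49-fold (log2 SE 0.08, adjusted p = 0.0256), from 12.93 ± 0.07 to 13.50 ± 0.04. Chmp4bl1 fell by 1.87 on the log2 scale (SE 0.21, adjusted p = 0.0131; n = 3 in control), Fbxo10 by 1.13 (SE 0.16, adjusted p = 0.0377) and Mefv by 0.98 (SE 0.12, adjusted p = 0.0131). These 8 genes were those with a symbol among 18 that passed in limma (12 higher, 6 lower), while 2750 had an unadjusted p under 0.05. Spots in masked areas were found for 3 of the 18. With 1 sample left out, Ccng1 passed in all 12 fits, Glo1 in 11, Mefv in 9 and Chmp4bl1 in 8. Coq7 and Rgs12 passed in 3 each, and Pdk1 and Fbxo10 in 2 each. Of the 18, 16 also passed in betamethasone minus control with the same sign. Independent lists would share 0.0219 higher and 0.00611 lower genes. The controls were shared, and unchanged groups simulated with shared controls gave 0 such genes, which says little, as hardly any gene passes in such groups. Across genes the correlation of the log2 changes was 0.645 (covariance 0.0584), against 0.499 (0.0198) in these simulations. With the control arrays split between the comparisons it was 0.192 and 0.214 (covariance 0.0239 and 0.0265).

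Immediate early and activity-regulated genes rose as a list in betamethasone with ketamine minus control. Of 36 members 28 were higher, with a median log2 change of 0.22 and a mean of 0.26 (camera adjusted p = 0.0280). The adjusted p was 0.854 with an estimated correlation, and 9 members passed over the list alone. In the deposited value table the list's median was −0.87, with the median of all genes at −1.03, and it was 0.17 after re-centring. Arc, of synaptic plasticity, was at 1.16 (SE 0.21, limma adjusted p = 0.0863), with 11.76 ± 0.17 in control and 12.92 ± 0.36 in the exposed group. Nr4a1 was at 0.82 (SE 0.16), Fos at 0.97 (SE 0.26), Jun at 0.70 (SE 0.16) and Junb at 1.38 (SE 0.32), none past the threshold over all genes. Arc and Nr4a1 had spots in masked areas of the array of ketamine samples 1 and 2. Each also had such spots on a control array, that of samples 3 and 4 for Arc and of samples 1 and 2 for Nr4a1. In betamethasone minus control 26 of 36 members were higher (median 0.12, and 0.08 in the re-centred value table, adjusted p = 0.357), with Arc at 0.91 (SE 0.21).

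Oligodendrocyte and myelin genes fell in betamethasone with ketamine minus control, with 17 of 23 members lower (median −0.31, mean −0.28, camera adjusted p = 0.00543). The list's median stayed below 0 under every scaling tried. In the deposited value table, whose scaling lowered all genes, that sign carries no weight. The adjusted p was 0.854 with an estimated correlation, and no member passed over the list alone. Cldn11, in part or whole in a masked area of the array of control samples 3 and 4, was at −1.13 (SE 0.39). Mag was at −1.11 (SE 0.40). Without the array of ketamine samples 1 and 2 the adjusted p was 0.437 for myelin (median −0.15) and 0.324 for immediate early genes (median 0.15). Without that of control samples 3 and 4 it was 0.0524 (median −0.29) and 0.313 (median 0.17). Without that of ketamine samples 3 and 4 it was 0.0519 for immediate early genes (median 0.26).

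Groups did not overlap for 2951 genes in that comparison (15.8%, against 2.86% by chance for independent samples, 8.66% in simulations with the array correlation, and 7.62% and 12.6% in the other splits that keep arrays whole). The count of 18 genes became 5 and 5 without control samples 1 and 3, 27 without control sample 4, 8, 7 and 7 without betamethasone samples 2, 3 and 4, 12 without betamethasone sample 1, and 27 and 11 without ketamine samples 1 and 2. It was 220 and 420 without the control arrays (samples 1 and 2, samples 3 and 4), 5 and 3 without the betamethasone arrays, and 114 and 3221 without the ketamine arrays, in the same order. The 3221 rest on the array with the dark area as the only ketamine array left.

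**Figure D3:**
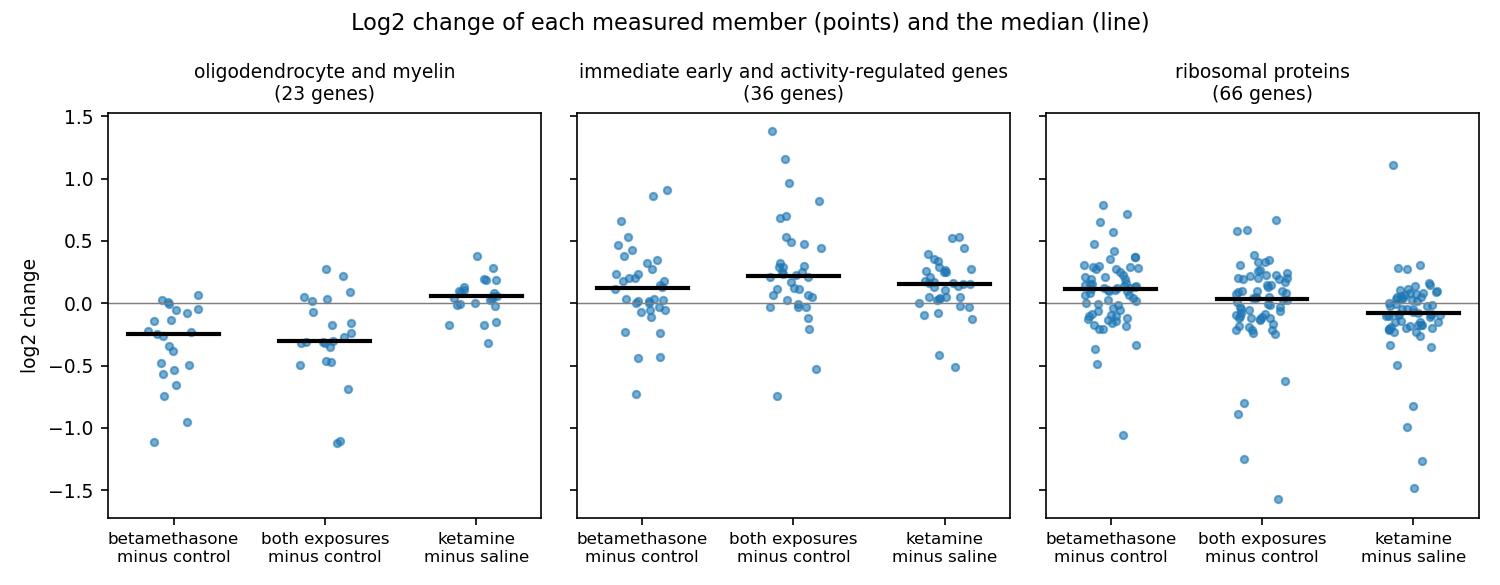
Log2 change of each measured member of 3 gene lists (oligodendrocyte and myelin, 23; immediate early and activity-regulated, 36; ribosomal proteins, 66) in the 3 comparisons. The line in each group of points is the list's median.

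Within betamethasone-exposed animals, no gene passed for ketamine minus saline in limma (0 genes, 649 with an unadjusted p under 0.05, smallest adjusted p = 0.174). The groups did not overlap for 757 genes (4.05%, against 2.86% by chance for independent samples, 8.66% in simulations with the array correlation, and 4.41% and 4.38% in the other splits that keep arrays whole). Capza3, an actin-capping subunit, was at 7.76 ± 0.05 after saline and 7.16 ± 0.05 after ketamine (n = 4 each, limma adjusted p = 0.174), that is at least 1.51-fold lower. Hmgb4 was at 8.24 ± 0.28 and 7.29 ± 0.02 (n = 4 each, limma adjusted p = 0.174), at least 1.93-fold lower. Neither was well above background in any ketamine sample, and both bounds equal the estimated changes, which did not pass. The other named genes had limma adjusted p = 0.875. Sash3, likewise with no ketamine sample well above background, was at least 1.48-fold lower (log2 change of its other probe 0.08). The log2 changes of the others were −0.65 for C5h1orf50, −0.94 for Ptprv, 0.66 for Map7, 0.51 for Lrrc75a, 0.75 for Rasip1 and 0.45 for Slc44a2 (other probe −0.06). Gabarapl2, of autophagy and receptor trafficking, was at 1.06 (SE 0.24, n = 3 after saline), with 0.0396 over the list alone and other probes at −0.08 and 0.32. The count was 13 and 16 without the betamethasone arrays (samples 1 and 2, samples 3 and 4), 28 and 2406 without the ketamine arrays in the same order, and 0 without any single sample or with only these groups, which shared a slide. The 2406 rest on the array with the dark area as the only ketamine array left, so ketamine and that array cannot be told apart there.

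Ribosomal protein genes fell as a list after ketamine: 42 of 66 members were lower, with a median log2 change of −0.08 and a mean of −0.10 (camera adjusted p = 0.00150). Their median stayed below 0 under every scaling tried. That sign carries no weight under loess with array medians of A, which put the median of all genes at −0.15. The adjusted p was 0.980 with an estimated correlation, and no member passed over the list alone. Rps15 at −1.49 (SE 0.68), Rps27a at −1.27 (SE 0.57), Rps19 at −0.99 (SE 0.43) and Rpl7 at −0.49 (SE 0.20) had the smallest p values. Each had spots in the dark area of the array of ketamine samples 1 and 2. Other probes of these genes were at 0.17 (Rps15), 0.02 (Rps27a), −0.31 and −0.06 (Rps19) and −0.00065 (Rpl7). With damaged areas masked the list still passed, at a median of −0.03 (camera adjusted p = 0.00283), and with the surface trend also removed at −0.06 (0.000191). Without the array of ketamine samples 1 and 2 the list's median was −0.02 (adjusted p = 0.264), and without the array of betamethasone samples 1 and 2 it was −0.04 (adjusted p = 0.102). Other lists did not pass with camera. Immediate early genes had 28 of 36 members higher (median 0.16, adjusted p = 0.277). They passed without the array of betamethasone samples 3 and 4 (median 0.20, adjusted p = 0.0130) and with damaged areas masked and the surface trend removed (0.0487). Loess with array medians of A, which put the median of all genes at −0.15, gave them −0.21. Sodium and calcium channels had 20 of 23 higher (median 0.11, with −0.12 under that loess, adjusted p = 0.303). Meningeal and vascular fibroblast genes had 12 of 16 lower (median −0.15, adjusted p = 0.277). They passed with 6 array means (adjusted p = 0.0219), processed signals (0.0106), damaged areas masked and the surface trend removed (0.0487), and without the array of betamethasone samples 1 and 2 (0.0374). Without the array of ketamine samples 1 and 2 their median was −0.41 (adjusted p = 3.94e-08), which rests on the 1 ketamine array left.

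No gene changed by betamethasone was moved back by ketamine past the threshold in limma (0 genes). As no gene passed in ketamine minus saline, this count could only be 0. Simulations of unchanged groups also gave 0, which says little, as hardly any gene passes in such groups. Of the 53 genes that passed in betamethasone minus control, 41 (77.4%) had the opposite sign in ketamine minus saline, and 9 of these had an unadjusted p under 0.05. Of the 2320 genes at an unadjusted p under 0.05 in betamethasone minus control, 74.3% had the opposite sign. Among genes selected in this way in simulations of unchanged groups, which share the betamethasone samples, 88.6% had the opposite sign. The number moved back was 12 and 16 without the betamethasone arrays (samples 1 and 2, samples 3 and 4), and 1 and 119 without the ketamine arrays, in the same order. The 119 rest on the array with the dark area as the only ketamine array left.

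Of the 21 genes of glutamate, GABA, glucocorticoid and melanocortin signalling and neuronal activity, none passed in any comparison in limma (0 genes). An unadjusted p under 0.05 was reached by 3 in betamethasone minus control, 0 in ketamine minus saline and 4 in betamethasone with ketamine minus control. In betamethasone minus control the log2 changes ran from −0.52 for the NMDA receptor subunit Grin2a (adjusted p = 0.235) to 0.91 for Arc (adjusted p = 0.119). Betamethasone minus control and ketamine minus saline share the betamethasone samples with opposite sign. Opposite values there can arise without any change (correlation across genes −0.50 in simulations of unchanged groups). The glucocorticoid receptor gene Nr3c1 was at −0.35, 0.31 and −0.04 in the 3 comparisons, and the mineralocorticoid receptor gene Nr3c2 at −0.36, 0.31 and −0.05. Sgk1 was at 0.06, 0.17 and 0.23, and Fkbp5, with spots in a masked area of the array of ketamine samples 1 and 2, at 0.04, −0.47 and −0.43. The glucocorticoid-induced Tsc22d3 was at −0.38, 0.42 and 0.04, and Crh, which encodes corticotropin-releasing hormone, at 0.40, 0.15 and 0.55 (n = 3 in control; other probe 0.04, 0.12 and 0.16). Grin1, of the NMDA receptor, was at 0.37, 0.03 and 0.39, and its other probe at −0.21, 0.15 and −0.06. The GABA-synthesizing Gad1 was at 0.14, 0.12 and 0.26, with its other probe at −0.29, 0.15 and −0.14, and Gad2 at −0.30, 0.40 and 0.10. The melanocortin receptor gene Mc4r was at 0.08, −0.04 and 0.05.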

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

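The tests of a damaged area on the array and of the control slide, the removal of the surface trend, the tests of myelin genes in betamethasone with ketamine minus control, the intervals over members, and the limit to splits that keep arrays whole were chosen only after the result was seen. In 8 of 181 groups of named genes (4.42%; chance gives about 1 in 20, that is 9.05) a single sample lay far from the others of its group. On the log2 intensity scale these were Apobec1 in control 1 (8.27, others 8.05 to 8.08), Chmp4bl1 in betamethasone 1 (11.20, others 10.98 to 11.02), Gria1 in control 2 (8.73, others 9.35 to 9.43) and Lrrc75a in control 4 (8.64, others 8.35 to 8.39). The others were Sash3 in ketamine 3 (7.21, others 7.30 to 7.31), Slc12a2 in ketamine 4 (10.17, others 9.94 to 9.98), Tmco5a in ketamine 3 (7.66, others 7.82 to 7.84) and Ugt8 in betamethasone 1 (7.61, others 7.83 to 7.87).

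The array of ketamine samples 1 and 2 stood apart from the other arrays in principal component 1. A damaged area on the array is a likely source: with the area found from probes of a single spot, copies of 650 other probes inside it were at a median of −1.34 log2 units from the copies of the same probe outside it, against −0.35 to −0.10 on the other arrays. Masking removed 78.6% of the array's lower correlation with the other arrays of its slide. The masked areas were chosen for departing from the other arrays, so such a gain was partly fixed in advance and carries little weight. The array's samples were still at −21.55 and −20.25 on principal component 1 of the masked values, against −6.13 to 37.56 for the others. A response to ketamine shared by both of its arrays was argued against as the main source. Outside the masked areas the departures of both ketamine arrays from the betamethasone arrays had a correlation of only 0.0675 across genes. The surface trend left on the array of ketamine samples 1 and 2 can lower this correlation, which was not computed with the trend removed. A smaller response to ketamine therefore stays open. With the surface trend also removed, 93.1% of the array's lower correlation with the others of its slide was gone. The trend was likewise measured as departure from the other arrays, so this gain too was partly fixed in advance. With the trend removed, ketamine samples 1 and 2 were at −8.63 and −8.37 on principal component 1 (others of the slide −9.87 to −4.25). On component 2 they were at 8.85 and 6.27 (others −13.51 to −3.67), so a smaller part stays open.

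Large differences from control, such as those of Ccng1, Glo1 and Chmp4bl1, were shared by both exposed groups. Prenatal betamethasone is 1 candidate explanation, and it stays open, as it was not tested apart from the slide. The control slide cannot be told apart from it, because 0 groups lay on both slides. The slides did differ in the spike-in RNA. Its slope on known amount was 0.492 and 0.542 on the control arrays and 0.873 to 0.881 on the others. The correlations were 0.891 and 0.908 against 0.987 to 0.992. Whether this difference between slides reached the genes named here was not tested. Probe-specific signal also cannot be told apart, because only 4 of the 53 called genes had another probe, with a median change of 0.173 of the called probe's and a range from −0.341 to 0.795. Ccng1 had no other probe.

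Myelin genes were lower in both exposed groups. A single array cannot be told apart as the cause, since medians nearest to 0 with 1 array left out were −0.19 in betamethasone minus control and −0.15 in betamethasone with ketamine minus control (adjusted p = 0.0889 and 0.437), that is 76.7% and 50.2% of the full medians, neither over 0.5 of these by more than its 95% interval over members. Spots in damaged areas were argued against in betamethasone minus control, with a median of −0.25 once these were masked, and cannot be told apart in betamethasone with ketamine minus control, where it was −0.27 (87.5% of the full median, likewise not beyond its interval). Prenatal betamethasone and the control slide may each account for the difference and stay open. No shift in the list passed with an estimated correlation (adjusted p = 0.846 and 0.854).

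Other splits of the same 8 samples into groups of 4 were run for the counts of genes and lists. Only 3 of the 35 splits keep both samples of every array together, as the real one does, which is too few for a share under 0.05. For betamethasone minus control, 2 of 35 splits gave as many genes (53 genes, highest of the others 722, and 0 among the others that keep arrays whole). The split with 722 genes set control samples 1 and 4 and betamethasone samples 2 and 4 against the rest, which divides every array. Such a split compares samples within arrays (array correlation 0.707), unlike the real one, so the 2 counts are not alike. It also nearly followed the dye, as all of these samples but control 1 were in Cy5. The cause of its count was not tested. For betamethasone with ketamine minus control, 1 of 35 splits gave as many genes, the real one (18 genes, highest of the others 15). With a real count of 0, every split gives as many, so the splits decide nothing for ketamine minus saline after betamethasone (35 of 35, highest of the others 1) and for the genes moved back by ketamine (100 of 100 drawn splits of the 12 samples, highest of the others 0). For gene lists, as many were given by 31 of 35 splits in betamethasone minus control (1 list, highest of the others 13), 32 in ketamine minus saline (1 list, highest 11) and 28 in betamethasone with ketamine minus control (2 lists, highest 12).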

How the results depend on the processing

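The alternatives with damaged areas masked, with the surface trend removed, with the value table re-centred and with crossed control numbers were chosen only after the data were seen; causes were not tested unless given. Of the 28 results for genes that passed, 751 of 1106 values under alternatives kept direction and side of the threshold, 344 no longer passed and 11 reversed. Of the 88 results for genes that did not pass, 3348 of 3473 values did not pass either, 110 passed and 15 passed with the other sign. Of the 11 reversed values 9, and all 15, came from the deposited value table, whose scaling lowered all genes; re-centred, it gave 0 of either kind. Ccng1 passed in 21 of 22 settings in betamethasone minus control and without each single sample and array (log2 change 2.84 to 2.97). The number of arrays, 2 per group, limited the precision, and signal over background limited the tests to 21523 of 30367 probes.

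In betamethasone minus control (53 genes) the count was 143 at an adjusted p under 0.10, 494 at an unadjusted p with at least 1.5-fold, 33 with detection in all 12 samples, 121 with Agilent processed signals (median of all genes in betamethasone with ketamine minus control moved to 0.12, against 0.18 with 75th percentile scaling), 101 with damaged areas masked (46 shared) and 379 with the surface trend also removed (45 shared). It was 0 under loess with array medians of A (median of all genes 0.18, and −0.15 in ketamine minus saline, with an array correlation of 0.939). It was 980 with no array block and 260 with only the 2 groups. With 6 array means, which take the array as the replicate (2 per group), it was 3. Leaving out 1 sample or array gave 3 to 533. In betamethasone with ketamine minus control (18 genes) these were 79, 755, 40 with no detection filter, 90 with 75th percentile scaling, 130 with processed signals, 47 masked (15 shared), 271 with the trend removed (15 shared), 0 with medians of A, 776 with no array block, 2 with only the 2 groups, 2 with array means, and 3 to 3221 leaving out 1 sample or array. The share of calls that were higher was 64.2% and 66.7%, against 53.3% and 50% with trend and robust moderation, 21.4% and 25% in the re-centred value table, 12.5% and 20% without control sample 1, and 85.6% with 75th percentile scaling in the latter comparison. In ketamine minus saline (0 genes, and 649 at an unadjusted p under 0.05) limma called 1 with the trend removed (Capza3, −0.56 with no ketamine sample well above background, adjusted p = 0.0401), 1 with no array block, 1 with no detection filter, 2 at offset 10, 2 with trend and robust moderation, 252 at an unadjusted p with at least 1.5-fold, and 0 to 2406 leaving out 1 sample or array. Genes moved back (0) were 1, 1, 1, 2 and 2 in the first 5 of these settings, 35 at an unadjusted p with at least 1.5-fold, and 0 to 119 leaving out 1 sample or array. The counts of 3221, 2406 and 119 came without ketamine samples 3 and 4, which left the array with the dark area as the only ketamine array.

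Replicate numbers of different groups did not pair (12 correlations from −0.13 to 0.04, 0 over 0.1). With a replicate block the count was 34 in betamethasone minus control and 14 in betamethasone with ketamine minus control, and 38 and 24 with control numbers crossed.

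The number of lists that passed in betamethasone minus control (1) was 3 with array means, 0 with an estimated correlation and 0 to 2 leaving out 1 array; in ketamine minus saline (1) 2 with array means, 2 with processed signals, 4 with the trend removed, 0 with an estimated correlation and 1 to 4 leaving out 1 array; and in betamethasone with ketamine minus control (2) 4 with array means, 3 with processed signals, 0 with an estimated correlation and 0 to 2 leaving out 1 array. In the last comparison mitochondrial oxidative phosphorylation genes (33 of 65 lower, median −0.0028, adjusted p = 0.0578, and 0.854 with an estimated correlation) passed with array means (0.0424), with processed signals (0.0128) and without the array of control samples 3 and 4 (median −0.14, adjusted p = 0.0121). In ketamine minus saline, cell cycle genes reversed from a median of 0.05 (camera adjusted p = 0.980) to −0.047 with the trend removed (adjusted p = 0.0487). Myelin genes were at 0.11 without the array of ketamine samples 1 and 2 (adjusted p = 0.00871), which rests on the 1 ketamine array left. Their main median was already above 0, at 0.06, though the main camera test had pointed down, far from the threshold (adjusted p = 0.980).

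In betamethasone minus control the deposited values gave 13476 genes (36 higher), and 13295 (30 higher) in betamethasone with ketamine minus control, since the column scaling of that table lowered all genes, with medians of −1.10 and −1.03. Re-centred, it gave 28 and 8. In that table these reversed in betamethasone minus control: Cd2bp2 −0.087, Cyp11b1 −0.28, Ddx56 −0.13, Fkbp5 −1.08, Gad1 −0.94, Glo1 −0.28, Gria1 −0.58, Mc4r −1.19, Mrps7 −0.31, Pdk1 −0.11 and Sgk1 −1.08. In betamethasone with ketamine minus control they were Bdnf −1.03, Coq7 −0.33, Egr1 −0.89, Gad1 −0.85, Gad2 −1.01, Gal3st1 −0.73, Glo1 −0.31, Gria1 −0.64, Gria2 −1.05, Mc4r −1.16, Rgs12 −0.52, Sgk1 −0.86 and Tsc22d3 −1.07. Slc44a2 in betamethasone minus control was at 0.24 with damaged areas masked and 0.17 with the trend removed, where its other probe was the one used.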

Other observations

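The values with damaged areas masked and those of the re-centred value table were chosen only after the data were seen. Endothelial, astrocyte and erythrocyte markers were mostly higher in both exposed groups, with none of these lists past the threshold in camera, while meningeal and vascular fibroblast genes had 8 of 16 and 6 of 16 members higher (medians 0.001 and −0.04). With 6 array means, endothelial genes passed in both comparisons (adjusted p = 0.0423 and 0.0424) and erythrocyte genes in betamethasone minus control (0.0375). Endothelial genes had 13 of 15 members higher in betamethasone minus control (median 0.19, adjusted p = 0.172) and 12 of 15 in betamethasone with ketamine minus control (median 0.23, adjusted p = 0.116), where Emcn, an endothelial sialomucin, was at 0.42 (SE 0.10, 0.0299 over the list alone). Astrocyte genes had 12 of 18 members higher (median 0.20, adjusted p = 0.357) and 15 of 18 (median 0.19, adjusted p = 0.532), with the intermediate filament gene Gfap at 0.50 and 0.70 (SE 0.24). Erythrocyte genes had 8 of 8 higher in betamethasone minus control (median 0.27, mean 0.35, adjusted p = 0.357) and 6 of 8 in betamethasone with ketamine minus control (median 0.25, adjusted p = 0.578). Each endothelial, astrocyte and erythrocyte median was below 0 in the deposited value table, whose scaling lowered all genes, and above 0 after re-centring.

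In betamethasone with ketamine minus control, microglial genes passed only without regard to direction (fry adjusted p = 0.0193; 14 of 20 higher, median 0.16, and 0.17 in the re-centred value table, camera adjusted p = 0.532). The complement gene C1qa was at 0.55 (SE 0.16, limma adjusted p = 0.207, 0.0489 over the list alone) and the lipid receptor gene Trem2 at 0.42 (SE 0.11, 0.0464 over the list alone). Neuropeptide genes passed likewise (fry adjusted p = 0.0229, median 0.06, mean −0.02), with the dynorphin precursor gene Pdyn at −0.87 (SE 0.21, 0.0345 over the list alone). As fry does not compare a list with other genes, these passes do not set the lists apart from the 2750 of 18672 genes with an unadjusted limma p under 0.05. The potassium channel gene Kcnq3 was at −0.76 (SE 0.17, 0.0415 over the list alone). With damaged areas masked, Arc (1.11, adjusted p = 0.0497), Nr4a1 (0.87, adjusted p = 0.0487) and the growth factor gene Hbegf (0.68, adjusted p = 0.0421) passed over all genes. In betamethasone minus control, the ATP synthase gene Atp5f1d was at 0.73 (SE 0.14, 0.0267 over its list alone) and the NF-kappaB inhibitor gene Nfkbia, a glucocorticoid-responsive gene, at 0.65 (SE 0.14, 0.0234 over its list alone).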
